A study of Flavobacterium columnare with 12 samples.

How the data were processed

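RNA was measured by strand-specific RNA sequencing in 12 libraries of Flavobacterium columnare isolate 94-081, with 3 biological replicates in each of 4 groups. Per the labels' protocols, an overnight culture was diluted into FCGM broth with or without 20 µg/ml of sterilised catfish mucus and grown for 48 h at 28 °C in separate flasks. The planktonic culture was taken off before the biofilm was harvested from the flask. RNA was stabilised, extracted on columns, treated with DNase and brought to 5 µg per sample, ribosomal RNA was depleted, and libraries were made with a directional kit, per the labels. The labels call the replicates biological, and they do not say whether a replicate number marks the same flask in the planktonic and biofilm groups.

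The authors deposited raw read counts per coding sequence for all 12 libraries in a single table, and these counts are whole numbers that sum to a different total in each library. The submitters' processing notes name Trim Galore 0.4.4, STAR and DESeq2 1.18.1, with no role or order given. The counter, its strand setting and its rule for reads in overlapping genes are not given in the sources used here. With a directional kit, a counting setting that ignored or reversed strand would mix or exchange the reads of genes on opposite strands, and the values in overlapping genes would be affected most. Of the 2778 coding sequences, 635 overlap a neighbour by their coordinates, and 557 of those were tested. Copies of transposase genes are near-identical in many genomes, so their values are uncertain where reads could be divided between copies. Coordinates are those of the deposited annotation on the sequence NZ_CP013992, and genes are named by the number after the annotation prefix 996.56 (peg.758, for example) with the deposited product name. All 2778 lengths are multiples of 3, so they are coding lengths. A reference genome was not used here.

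Counts were analysed in R 4.3.3 with edgeR 4.0.16. Coding sequences with too few counts were removed by filterByExpr (minimum count 10, minimum total 15, by group), which left 2590. Libraries were scaled by the trimmed mean of M values, with factors from 0.945 to 1.07. A quasi-likelihood model (glmQLFit and glmQLFTest) with 1 coefficient per group was fitted to all 12 libraries, since the 4 groups then share an estimate of spread (common dispersion 0.0339). A gene passed at a Benjamini-Hochberg adjusted p below 0.05 over the tested genes, with no minimum fold. All adjusted p-values for genes come from this edgeR test unless another is named. The contrasts were biofilm against planktonic without mucus and with mucus, mucus against no mucus in planktonic cells and in biofilm, and the interaction, which is the difference between the first 2 of these.

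Fixed lists of genes were drawn up by patterns on the product name, and all 30 had at least 3 tested members. Lists were tested with camera in limma 3.58.1 with a preset correlation between members of 0.01, adjusted over the lists. The test was repeated with the correlation estimated from the data and with fry, which asks whether a list's own genes move and does not compare them with other genes. Of the 9, 4, 1 and 7 lists that passed in the 4 comparisons of 2 groups, 1, 1, 0 and 0 kept their call with an estimated correlation. The list test of the interaction was added after the gene test of the interaction had been seen.

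The test, the libraries in the fit, the lists, the rule for naming genes and most other settings were set before the data were examined. The rule took, per comparison, the 6 largest rises and 6 largest falls among passing genes with a mean of at least 10 CPM, groups that did not overlap and a product that is not only hypothetical. It added up to 3 changed members with the smallest adjusted p of each list that passed or had at least 3 changed members. It also added the hypothetical protein with the largest rise and the one with the largest fall, and the 3 coding sequences with the highest mean in each group. For the interaction it took up to 4 genes in each direction, without the condition on overlap. This gave 83, 95, 57 and 56 genes for the comparisons of 2 groups and 7 for the interaction, of which a part is named. Named outside the rule, after their values were seen, were list members that went against their list or are not part of what its name says (peg.157 and peg.1040 without mucus, peg.459 and peg.783), peg.2750 in biofilm, the interaction genes peg.5, peg.1212 and the stretch from peg.2232 to peg.2236, and the neighbouring genes of the regions described under the other observations.

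Replicates within a group differed by more than sampling noise. Chi-square per degree of freedom between replicate libraries was 99.4 to 164 without mucus and 11.6 to 27.2 with it. This value also grows with depth. Totals reached 13065240 without mucus and 6596744 with it, so the ranges do not compare spread alone. Spearman correlations were 0.969 to 0.990 without mucus and 0.994 to 0.997 with it. The shared estimate of spread covers both, so p-values could be too small without mucus and too large with it. Library totals ran from 2395239 to 13065240. The steps were tested on simulated counts with the real means and totals of 2590 genes. Of these, 200 were changed by the folds below and 20 more were raised 1.5-fold as a list. In the 4 comparisons of 2 groups 1.5-fold changes were found in 32.8% to 38.8% of cases, 2-fold in 76.1% to 86.6% and 4-fold in 97.0% to 100%. For the interaction the shares were 8.96%, 56.7% and 98.5%. Unchanged genes made up 6 to 8 of the 154 to 165 calls per comparison of 2 groups, and 6 of the 117 for the interaction. The simulated libraries were independent and had the same spread per gene in all 4 groups. The real ones differ in spread and some deviate together, so these shares may not carry over to them. Smaller changes were therefore often not detectable at this depth and number of replicates.

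Whether replicate numbers pair the samples was checked from deviations around group means. For biofilm and planktonic cells without mucus the correlations of same-numbered libraries were 0.534, 0.120 and 0.345, all above 0.1, so by this criterion the numbers pair those samples, and a fit with the number as a block is given where it changed a call. The criterion is weak. The second pair did not match best with its own number. Deviations around a group mean also sum to 0, so a deviation shared by the third libraries alone could raise the other correlations.

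Other settings chosen beforehand were DESeq2 size factors in edgeR, total count only, no filter on low counts, the Wald test of DESeq2 1.42.0, only the libraries compared in the fit, the replicate block, a stricter adjusted p of 0.01, a minimum fold of 2, and each library left out in turn. Added after seeing the data were leaving out the third planktonic and the third biofilm library without mucus together, removing the trend against coding length, thinning every library to the shallowest total, and a replicate block within each treatment. Other splits of the samples were counted, 10 for each comparison of 2 groups, 100 drawn for the interaction, and 10 more for it that exchanged the planktonic and biofilm library of 1 treatment and number together. The covariance that same-numbered libraries give the mucus differences without any effect was estimated from their deviations from the group means in log2 CPM, taking libraries of different numbers as independent. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.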

Results

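RNA levels were measured in Flavobacterium columnare isolate 94-081, a gliding Gram-negative bacterium of the group that causes columnaris disease in freshwater fish. Cells were grown for 48 h at 28 °C as free-swimming planktonic cultures or as biofilm, in broth alone or in broth with 20 µg/ml of sterilised catfish mucus. The 4 groups held 3 biological replicates each, and the 12 libraries gave counts for 2778 coding sequences. Total counts were 10604276, 12285106 and 4142181 in planktonic cells, 13065240, 12688597 and 2395239 in biofilm, 5405519, 4544705 and 4737257 in planktonic cells with mucus, and 5507983, 6596744 and 5138533 in biofilm with mucus. The first principal component held 46.1% of the variance and separated biofilm from planktonic libraries. The second held 25.4% and placed the 6 libraries with mucus above the 6 without. The third planktonic and the third biofilm library without mucus, also the shallowest of their groups, lay lowest on it, at -23.0 and -17.4. Levels are given in CPM (counts scaled to the normalised library total) as mean ± SD with n = 3 per group. Changes are log2 fold changes with a standard error (SE), derived as the absolute change divided by the square root of the F value of the test. Dps peg.1273, FeoB peg.2639, PorT peg.2266, peg.63, peg.171 to peg.173, peg.195, peg.2568 and peg.2750 overlap a neighbouring coding sequence at an end, so some of their reads could not be assigned with certainty.

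**Figure D1:**
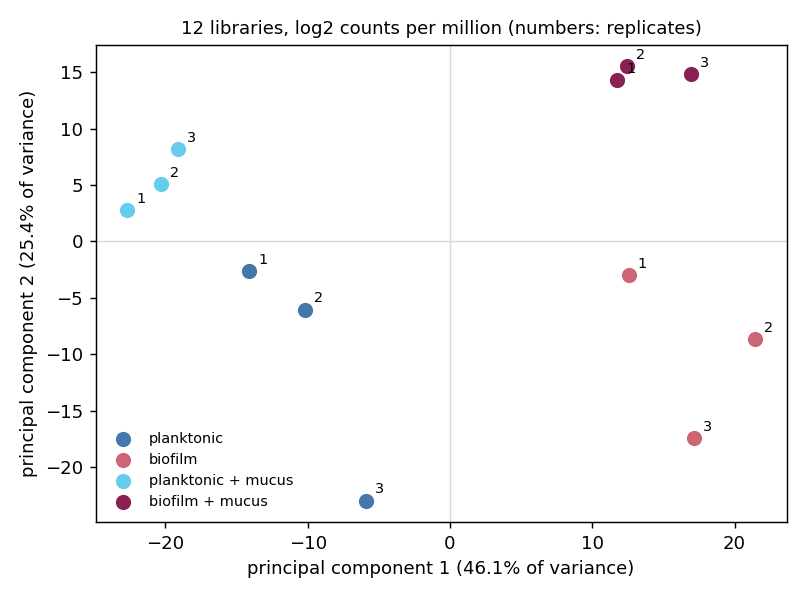
Principal components of the 12 libraries from log2 CPM; the axes carry 46.1% and 25.4% of the variance, colours mark the 4 groups and numbers the replicates. All 6 biofilm libraries lie to the right of all 6 planktonic ones, and the third planktonic and the third biofilm libraries without mucus lie lowest.

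The comparison of biofilm with planktonic cells without mucus asked which genes differed between attached and free-swimming growth. Among the genes far higher in biofilm were single genes for catalase, for the DNA-binding protein Dps and for receptors of hemin and siderophores. The catalase gene peg.758 (901726–903195), whose product breaks down hydrogen peroxide, was at 1485 ± 1612 CPM in biofilm and 32.7 ± 12.2 in planktonic cells. The log2 change was 5.53 (SE 0.72, adjusted p = 0.000862), and the third biofilm library held 3346 CPM. The DESeq2 test gave this catalase gene no adjusted p, here or with mucus. The hemin receptor peg.1530 (1796051–1798117) stood at 496 ± 319 against 18.1 ± 16.9 CPM, a change of 4.88 (SE 0.65, adjusted p = 0.000871). Dps peg.1273 (1479247–1479729), a protein that binds DNA and stores iron, rose from 64.5 ± 20.3 to 1000 ± 109 CPM, a change of 3.95 (SE 0.20, adjusted p = 1.11e-06). In the other direction, MoaA peg.1151 (1344592–1345581), an enzyme of molybdenum cofactor synthesis, fell from 53.2 ± 11.5 to 12.7 ± 5.44 CPM, a change of -2.08 (SE 0.32, adjusted p = 0.0017).

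In all, 614 of 2590 tested genes passed the test, 327 higher and 287 lower in biofilm, and 89 and 35 of them by at least 2-fold. The groups did not overlap for 30.8% of tested genes, where chance gives 10%. With scaling by total count alone the split was 225 higher and 399 lower, and the median change of all genes moved from -0.0067 to -0.11, so directions hold relative to that shift. With only the 6 libraries compared in the fit, 113 genes passed. In that fit 55 of the 81 passing genes picked for naming lost their call, and peg.758, peg.1530, peg.1273 and peg.1151 kept it. Without the second biofilm library 351 genes passed.

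Iron and heme uptake genes rose as a group (8 of 18 tested members higher and none lower, 8 when adjusted over the list alone; adjusted p = 1.46e-06). This list kept its call when the correlation between members was estimated (adjusted p = 0.0124 with an estimated correlation). Its median log2 change was 1.01 with all libraries and 0.42 with the third planktonic and the third biofilm library both left out. Its risers included the siderophore receptor peg.2093 (2450356–2452461; 992 ± 602 against 54.6 ± 41.2 CPM, log2 change 4.22), beside the hemin receptor and Dps. The iron-regulated membrane protein peg.2094 next to the siderophore receptor changed by 4.28. The neighbour of the hemin receptor, hypothetical protein peg.1531, had the largest rise of any hypothetical protein (5.14). Oxidative stress genes also rose (11 higher and 2 lower of 40, 11 and 3 adjusted over the list alone; adjusted p = 5.03e-05). That call was lost with an estimated correlation (adjusted p = 0.102 with an estimated correlation). Beside peg.758 its risers were the second catalase peg.757 (4.89), the AhpC-like peroxidase peg.759 (903571–904206; 3071 ± 819 against 456 ± 117 CPM, 2.75, adjusted p = 3.66e-05) and thioredoxin peg.2418 (1.43, adjusted p = 3.66e-05). The 2 members that fell were cytochrome c peroxidases, peg.157 and peg.1040 (-0.67 and -1.12). Dps belongs to both lists.

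Ribosomal protein genes were higher in biofilm for 23 of 53 members and lower for none (29 higher adjusted over the list alone; median log2 change 0.51, adjusted p = 3.90e-08). The call was lost with an estimated correlation (adjusted p = 0.573 with an estimated correlation). Examples were S15 peg.555 (4469 ± 674 against 2373 ± 552 CPM, log2 change 0.91), S6 peg.1205 (0.88) and L25 peg.2378 (0.49). Under total-count scaling 15 of the 53 passed, all higher. Of 76 two-component and transcription regulators 13 were higher and 7 lower (14 and 8 adjusted over the list alone), and the list did not pass (median 0.03, or -0.07 under total-count scaling; adjusted p = 0.467). Its members with the smallest adjusted p were the AraC-family regulator peg.1459 (2.34, adjusted p = 6.0e-05), the LuxR-type response regulator peg.2210 (1.46) and the response regulator peg.43 (2.32). The Xaa-Pro aminopeptidase peg.2659 (3159021–3160313), which removes the residue before proline from peptides, was at 9094 ± 5088 against 2157 ± 318 CPM (2.08, SE 0.37, adjusted p = 0.00352). With only the libraries compared in the fit its adjusted p was 0.058, and that of S15 and L25 was 0.0661 and 0.0834.

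Of the other 6 lists that passed, tRNA-charging and branched-chain amino acid synthesis genes were higher, and chaperone, low-oxygen respiration, protease and gliding genes were lower. Aminoacyl-tRNA synthetases were higher for 7 of 21 and lower for none (7 adjusted over the list alone; adjusted p = 0.0175, and adjusted p = 0.705 with an estimated correlation), among them isoleucyl-tRNA synthetase peg.216 (0.54) and lysyl-tRNA synthetase peg.1789 (0.42). Branched-chain amino acid synthesis genes were higher for 5 of 10 (5 adjusted over the list alone; adjusted p = 0.0175, and adjusted p = 0.566 with an estimated correlation), led by the aminotransferase peg.1874 (32.7 ± 8.49 against 11.9 ± 2.22 CPM, 1.47). Chaperones were higher for 2 and lower for 7 of 20 (2 and 10 adjusted over the list alone; adjusted p = 0.0175, and adjusted p = 0.716 with an estimated correlation). HtpG peg.1463 fell from 9563 ± 629 to 5209 ± 1282 CPM (-0.88), and HtrA peg.1740, a periplasmic protease as well as a chaperone, changed by -0.57. Low-oxygen and denitrification genes were higher for 1 and lower for 5 of 20 (2 and 7 adjusted over the list alone; adjusted p = 0.0175, and adjusted p = 0.716 with an estimated correlation), including NosY peg.1807 of nitrous oxide reductase maturation (-0.91) and the cbb3 oxidase assembly protein peg.1307 (-0.85). The riser there was the Crp/Fnr-family regulator peg.1313 (0.38), which lost its call without the second planktonic library (adjusted p = 0.13), the third planktonic (0.068) or the first or second biofilm library (0.11 and 0.052), under total-count scaling (0.126) and with every library thinned to the shallowest total (0.127). Proteases were higher for 3 and lower for 17 of 65 (4 and 18 adjusted over the list alone; adjusted p = 0.0175, and adjusted p = 0.496 with an estimated correlation), for example the zinc metalloproteases peg.195 (-0.75) and peg.2409 (-0.72). Gliding and type IX secretion genes, which drive surface movement and protein export in this phylum, were higher for 1 and lower for 7 of 14 (2 and 9 adjusted over the list alone; adjusted p = 0.0215, and adjusted p = 0.566 with an estimated correlation). GldG peg.1940 changed by -0.55 and PorT peg.2266 by -0.52, while the riser, peg.459 (0.71), is a secreted protein with a type IX target domain and not a part of the machinery. All 6 calls were lost without the first planktonic library (adjusted p = 0.0685 to 0.129) or without the third biofilm library (0.0547 to 0.283). Some were also lost without the second planktonic (gliding 0.0658, branched-chain 0.0698) or the second biofilm library (tRNA synthetases 0.0604, branched-chain 0.0604, low-oxygen 0.0732). In those fits the medians of the lost lists kept their direction, at 0.439 to 1.36 times their size. With only the libraries compared in the fit, 9 of the genes named in these lists had adjusted p from 0.0512 to 0.167, whereas peg.1874, peg.195 and peg.2409 kept their calls. With the third planktonic and the third biofilm library both left out the tRNA synthetase, chaperone and branched-chain calls were lost (adjusted p = 0.0518, 0.147 and 0.277), with medians of 0.21, -0.33 and 0.41 against 0.20, -0.49 and 0.68. With thinned libraries the branched-chain call was lost (0.121) at a median of 0.80. Genes for histidine, tryptophan and arginine synthesis missed the threshold (5 higher and 2 lower of 18, adjusted p = 0.0531). They passed with the replicate number as a block (adjusted p = 0.0311) or as a block within each treatment (0.0102), but also under DESeq2 size factors (0.045), total-count scaling (0.0402), no filter (0.044) and removal of the length trend (0.0486), and without the third planktonic (0.00142), the first biofilm (0.0301) or both the third planktonic and the third biofilm library (0.00223).

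**Figure D2:**
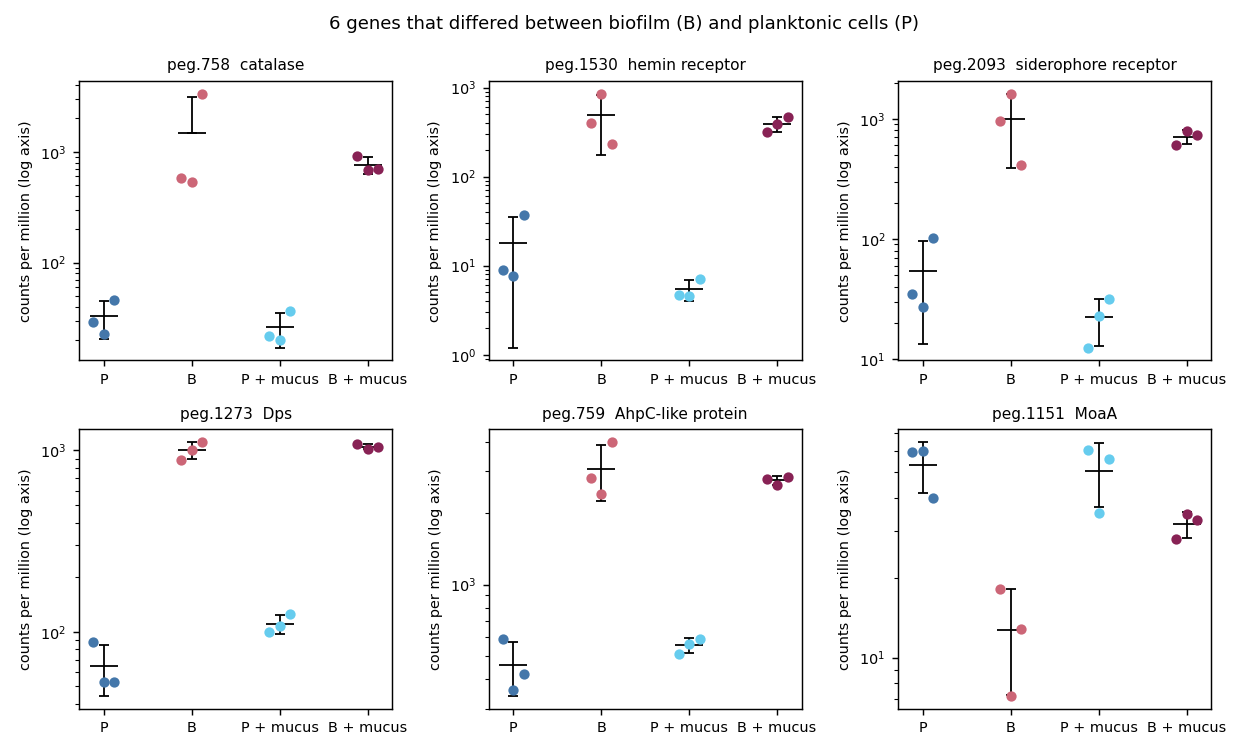
CPM on a log axis of 6 genes in planktonic cells (P) and biofilm (B) with and without mucus; points are libraries, the long line is the mean and the bars are ± 1 SD of 3 libraries, with only the upper bar drawn where the SD exceeds the mean. The first 5 genes are higher in every biofilm library than in every planktonic one, and MoaA is lower.

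With mucus in the broth, single iron receptor and catalase genes were again among those far higher in biofilm than in planktonic cells. The hemin receptor peg.1530 was at 393 ± 73.1 against 5.47 ± 1.44 CPM, a log2 change of 6.17 (SE 0.71, adjusted p = 0.000148), and its neighbour peg.1531 changed by 7.07. The siderophore receptor peg.2093 stood at 707 ± 91.6 against 22.2 ± 9.49 CPM (5.00, adjusted p = 0.000243), catalase peg.758 at 767 ± 132 against 26.2 ± 9.14 CPM (4.87, SE 0.70, adjusted p = 0.000485) and Dps peg.1273 at 1045 ± 32.6 against 111 ± 13.6 CPM (3.24, adjusted p = 3.53e-06). A sensor kinase and a response regulator encoded close together, peg.915 (1093938–1095272) and peg.918, rose by 3.59 and 2.60. The gene that fell most by the naming rule was 4-hydroxybutyrate coenzyme A transferase peg.342 (419669–420943), from 1150 ± 163 to 337 ± 13.4 CPM (-1.77, SE 0.18, adjusted p = 0.000102).

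This comparison had 907 genes past the threshold, 447 higher and 460 lower in biofilm, with 179 and 46 of them at least 2-fold. The groups did not overlap for 62.4% of tested genes against 10% by chance. Total-count scaling gave 340 higher and 607 lower and moved the median of all genes from -0.0074 to -0.11. With only these 6 libraries in the fit 1389 genes passed, and without the third biofilm library with mucus 569 passed.

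Ribosomal protein genes were higher for 35 of 53 and lower for none (36 adjusted over the list alone; median 0.76, adjusted p = 3.17e-13, and adjusted p = 0.619 with an estimated correlation). S18 peg.1204 rose by 1.52 and S6 peg.1205 by 1.49, and 32 of the 53 were higher under total-count scaling. Elongation factor Tu peg.1773 had the highest mean in this group, 22588 ± 1447 against 13445 ± 216 CPM (0.75, adjusted p = 0.00316). Transcription and translation factors as a list did not pass (11 higher and 2 lower of 21, adjusted p = 0.18), although release factor 3 peg.1762 and NusG peg.1771 rose by 0.87 and 0.74. Iron and heme genes were higher for 7 of 18 and lower for none (8 adjusted over the list alone; adjusted p = 6.91e-05, and adjusted p = 0.033 with an estimated correlation), including FeoB peg.2639 (332 ± 14.4 against 102 ± 12.1 CPM, 1.70). Oxidative stress genes were higher for 12 and lower for 4 of 40 (13 and 5 adjusted over the list alone; adjusted p = 0.00943, and adjusted p = 0.311 with an estimated correlation). The peroxidase peg.759 rose by 2.31, whereas the cytochrome c551 peroxidase peg.157 (173256–174278), a periplasmic enzyme that draws electrons from the respiratory chain, fell from 3915 ± 688 to 1259 ± 158 CPM (-1.64). Proteases were higher for 7 and lower for 20 of 65 (7 and 21 adjusted over the list alone; adjusted p = 0.00943, and adjusted p = 0.311 with an estimated correlation), with HtrA peg.1740 at -0.90 and the tail-specific protease peg.2294 at -0.95. These 4 lists passed with each library left out in turn.

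Other named falls were in NAD synthesis (quinolinate synthetase peg.482, -1.74, and L-aspartate oxidase peg.481, -1.52), and in oxygen-independent heme synthesis (coproporphyrinogen oxidase peg.1232, -1.61). The list of stationary phase and starvation genes did not pass (1 higher and 4 lower of 5, the same adjusted over the list alone; adjusted p = 0.68). Its riser was Dps, and its falls included PhoH peg.1936 (-1.19) and polyphosphate kinase peg.1045 (-0.93). The cbb3 oxidase subunit CcoN peg.1310, of a terminal oxidase used at low oxygen, was at 5280 ± 144 against 9977 ± 1453 CPM (-0.92). Gliding genes were higher for 2 and lower for 7 of 14 with adjusted p = 0.099 for the list, and GldJ peg.2177 fell by 0.72 on the log2 scale. Of 9 glycan-degrading enzymes 4 were higher and none lower (adjusted p = 0.12 for the list), among them chondroitinase peg.1636 (1912180–1914864; 5869 ± 1266 against 2847 ± 426 CPM, 1.04, adjusted p = 0.00357), which cleaves a connective-tissue polysaccharide, and the BNR-repeat glycosyl hydrolase peg.1316 (1.66). Hypothetical protein peg.2295, at 14134 ± 2083 against 5417 ± 1489 CPM, was another of the most abundant transcripts (1.38).

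**Figure D3:**
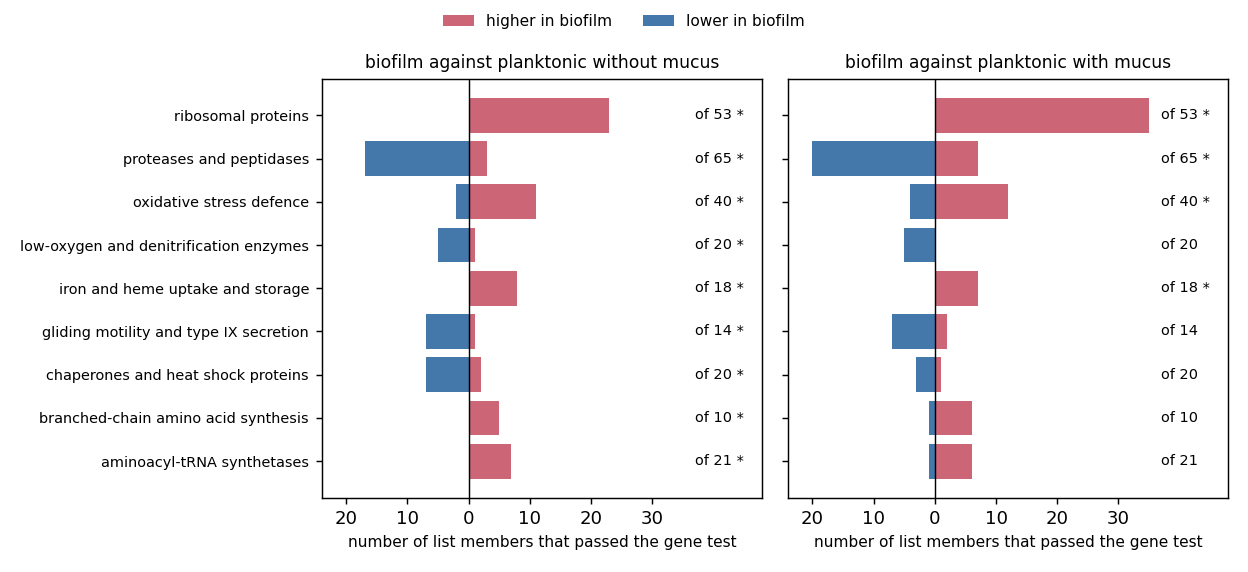
Number of members of 9 gene lists that passed the gene test in biofilm against planktonic cells without mucus (left) and with mucus (right), higher to the right of 0 and lower to the left; the number of members tested stands at the right and an asterisk marks lists that passed the list test. Ribosomal proteins had 23 and 35 members higher and none lower.

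The state differences with and without mucus came from separate libraries. They shared 218 genes higher in biofilm (56.4 by chance overlap of independent lists) and 181 lower (51.0), and 3 genes passed in opposite directions. Both sets of calls came from the same fit with a shared spread per gene, which these chance values do not allow for. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.739.

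In planktonic cultures with mucus a group of neighbouring genes was higher than without it. Ribose-phosphate pyrophosphokinase peg.173 (187656–188486), which makes the sugar phosphate for nucleotide synthesis, rose from 196 ± 37.7 to 818 ± 217 CPM (log2 change 2.06, SE 0.21, adjusted p = 0.000688). Its neighbours peg.172, peg.171 and ribonuclease Z peg.170 (185635–186198) rose by 2.06, 1.85 and 1.55. The cytochrome c551 peroxidase peg.157 rose from 1672 ± 162 to 3915 ± 688 CPM (1.23, adjusted p = 0.00599), and the dTDP-rhamnose epimerase peg.63 (78496–79047), an enzyme of surface sugar synthesis, fell from 690 ± 39.6 to 423 ± 49.4 CPM (-0.71, adjusted p = 0.00599). These 6 genes passed in every alternative fit and with each library left out.

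With 173 higher and 151 lower, 324 genes passed, of which 43 and 27 changed at least 2-fold. The groups did not overlap for 38.0% of tested genes against 10% by chance. The count depended on single libraries. It was 11 without the third library with mucus, 38 without the second, 147 without the first, 67 without the second planktonic library without mucus, 110 without the third and 512 without the first, and 101 with only the 6 libraries compared. More genes were lower than higher without the first (286 and 226) or the second planktonic library (39 and 28). Without the third library with mucus, 48 of the 54 passing genes picked for naming lost their call.

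Nitrous-oxide reductase NosZ peg.1812 (2119161–2121134), which reduces nitrous oxide to nitrogen gas, was at 2110 ± 392 against 763 ± 268 CPM (1.47, adjusted p = 0.019), and CcoN peg.1310 at 9977 ± 1453 against 5902 ± 603 CPM (0.76, adjusted p = 0.0244). Both lost the call without the second or the third library with mucus (adjusted p = 0.066 and 0.077 for NosZ, 0.074 and 0.11 for CcoN) or the second planktonic library (0.056 and 0.071). Low-oxygen genes were higher for 5 of 20 and lower for none, with adjusted p = 0.16 for the list. Carbonic anhydrase peg.564 (686791–687474) rose from 84.1 ± 7.37 to 251 ± 84.9 CPM (1.58, adjusted p = 0.0111; 0.054 without the third library with mucus). The largest falls were in an arginine synthesis locus, with argininosuccinate synthase peg.2750 (3286533–3287744) at 34.2 ± 6.74 against 597 ± 865 CPM (-4.12, SE 0.99, adjusted p = 0.0293). The third planktonic library held 1596 CPM there, and without it the change was -1.51 and passed at adjusted p = 0.049. Without the first, second or the third library with mucus the call was lost (0.078, 0.092 and 0.11). Its neighbours peg.2752 and peg.2753 went from -3.46 to -0.83 and from -3.48 to -0.91 without the third planktonic library and lost their calls (adjusted p = 0.24 and 0.30). They were also lost without any 1 library with mucus (0.106 to 0.155), and with only the libraries compared all 3 genes missed the threshold (0.0746, 0.0955 and 0.0936).

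Ribosomal proteins were the list that passed, lower for 8 of 53 and higher for none (9 adjusted over the list alone; median -0.42, adjusted p = 7.34e-09). The call was lost with an estimated correlation (adjusted p = 0.757 with an estimated correlation) and in the direction test of fry (adjusted p = 0.103), though it stood with each library left out. L25 peg.2378 changed by -0.46 and S4 peg.2049 by -0.64. Those single-gene calls were lost without the second library with mucus (adjusted p = 0.075 and 0.096) or the third (0.077 and 0.14), and S4 also without the first (0.10) and without the second or the third planktonic library (0.11 and 0.11), with only the libraries compared (0.0634) and with thinned libraries (0.053). Fatty acid synthesis genes were higher for 1 and lower for 5 of 29, with adjusted p = 0.066 for the list.

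**Figure D4:**
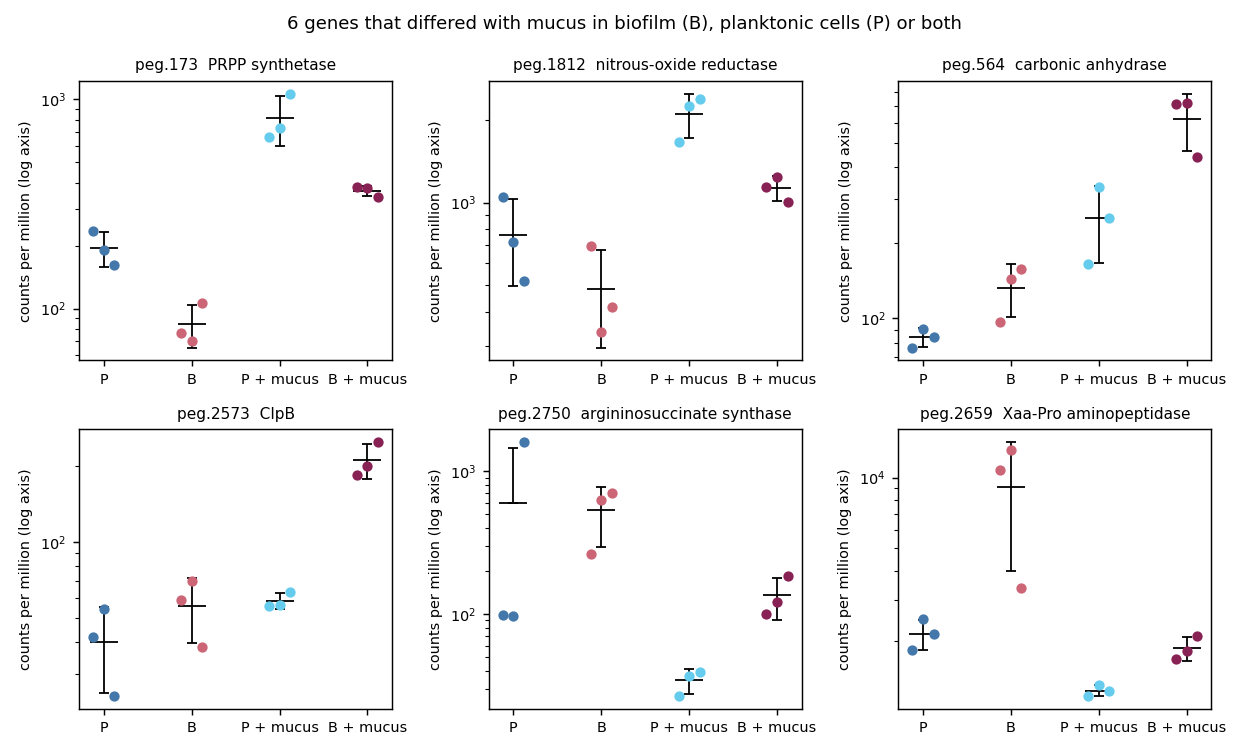
CPM on a log axis of 6 genes in planktonic cells (P) and biofilm (B) with and without mucus; points are libraries, the long line is the mean and the bars are ± 1 SD of 3 libraries, with only the upper bar drawn where the SD exceeds the mean. The planktonic mean of peg.2750 without mucus rests on the third library, at 1596 CPM.

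Carbonic anhydrases, the same pyrophosphokinase locus and effector-type Vgr genes were higher in biofilm with mucus than without it. Carbonic anhydrase peg.565 (687480–688115), which interconverts carbon dioxide and bicarbonate, rose from 267 ± 17.8 to 1772 ± 214 CPM (log2 change 2.73, SE 0.16, adjusted p = 5.13e-06), and its neighbour peg.564 from 132 ± 31.5 to 625 ± 161 CPM (2.24, adjusted p = 0.000449). Pyrophosphokinase peg.173 rose from 84.6 ± 19.6 to 367 ± 20.6 CPM (2.13, SE 0.22, adjusted p = 0.000203), and the TonB-dependent receptor peg.467 (577329–579986) from 5.8 ± 0.997 to 49.6 ± 6.49 CPM (3.11, SE 0.32, adjusted p = 0.000203). The Xaa-Pro aminopeptidase peg.2659 fell from 9094 ± 5088 to 1866 ± 222 CPM (-2.29, SE 0.37, adjusted p = 0.0025). NADH dehydrogenase subunits N, M and L (peg.314, peg.313 and peg.312) fell together, with changes of -0.78, -0.64 and -0.63 (adjusted p = 0.00127, 0.00219 and 0.00295). All of these kept their calls in every alternative fit.

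The count was 330, with 209 higher and 121 lower, 115 and 17 of them at least 2-fold. The groups did not overlap for 36.6% of tested genes against 10% by chance. It was 125 without the second library with mucus, 166 and 183 without the first and the third, and 174 without the second biofilm library without mucus. With the third planktonic and the third biofilm libraries without mucus both left out, 528 passed, 273 higher and 255 lower.

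Type VI secretion and Rhs genes, a contact-dependent injection system and its effectors, were higher for 3 of 7 and lower for none (3 adjusted over the list alone; adjusted p = 0.0269, and adjusted p = 0.559 with an estimated correlation). The members were the Vgr spike proteins peg.357 (439241–441154; 2.13, adjusted p = 0.000888), peg.2621 (3113816–3115921; 72.4 ± 22.2 to 235 ± 48.7 CPM, 1.68) and peg.549 (1.54), and the list's median was 0.04 against a mean of 0.72. Low-oxygen genes were higher for 4 and lower for 2 of 20 (10 and 2 adjusted over the list alone; adjusted p = 0.0269, and adjusted p = 0.647 with an estimated correlation). NosZ peg.1812 was at 1130 ± 119 against 483 ± 188 CPM (1.22, adjusted p = 0.0211), a call lost without the second or the third biofilm library (adjusted p = 0.069 and 0.052) or the first or second with mucus (0.059 and 0.074). The members that fell were Crp/Fnr-family regulators, peg.783 (-0.68) and peg.1255 (-0.54). Lower lists were aminoacyl-tRNA synthetases (0 higher and 3 lower of 21, 4 lower adjusted over the list alone; adjusted p = 0.0269, and adjusted p = 0.647 with an estimated correlation), with aspartyl-tRNA synthetase peg.2416 at -0.71, and glycolysis (2 lower of 16, 3 adjusted over the list alone; adjusted p = 0.0269, and adjusted p = 0.559 with an estimated correlation). The glycolysis members were glyceraldehyde-3-phosphate dehydrogenase peg.1058 (-0.78) and peg.1894, the acetyltransferase of pyruvate dehydrogenase (-0.43), which links glycolysis to the citric acid cycle. The peg.1894 gene lost its call without the second or the third biofilm library (adjusted p = 0.099 and 0.051) or any library with mucus (0.086, 0.099 and 0.092), and with only the libraries compared (0.0739). Branched-chain amino acid synthesis was lower for 2 of 10 (2 adjusted over the list alone; adjusted p = 0.0366, and adjusted p = 0.647 with an estimated correlation), both aminotransferases, of which peg.1374 (-0.59) kept its call with each library left out. Polysaccharide and envelope glycan synthesis was lower for 2 of 64 (0 adjusted over the list alone; adjusted p = 0.0269, and adjusted p = 0.647 with an estimated correlation), the lipid A exporter MsbA peg.1829 (-0.46) and a glycosyl transferase, peg.1968 (-0.44). MsbA lost its call without the second biofilm library (0.058) or the second or the third with mucus (0.072 and 0.065), and peg.1968 without the first or the third biofilm library (0.06 and 0.092) or the first or second with mucus (0.14 and 0.10), and under 5 other settings (0.054 to 0.279). Histidine, tryptophan and arginine synthesis passed with no member past the gene test, over all genes or adjusted over the list alone, of 18 (median -0.27, mean -0.96; adjusted p = 0.0269, and adjusted p = 0.559 with an estimated correlation). All 7 list calls were lost without the third biofilm library without mucus (adjusted p = 0.0995, and 0.368 for the branched-chain list). The branched-chain call was also lost without the second biofilm library (0.0646) or the first or second with mucus (0.124 and 0.123), the histidine, tryptophan and arginine call without the second biofilm library (0.0539), and the polysaccharide and type VI calls without the first library with mucus (0.0534 and 0.0627). The glycolysis call was lost without the third with mucus (0.0578). In those fits the medians of the lost lists stayed at 0.679 to 1.07 times their size, except for the type VI list. The type VI mean was 0.63 and 0.65 against 0.72, and its median 0.01 and 0.02 against 0.04. The mean of the branched-chain list was -0.21 to -0.25 where it was lost, against -0.40 with all libraries. With the third planktonic and the third biofilm library both left out the histidine, tryptophan and arginine list alone of the 7 passed (adjusted p = 0.000633), and the others had 0.0609 to 0.41. Their medians were then -0.15 for tRNA synthetases (-0.19 with all libraries), 0.55 for low-oxygen genes (0.69), -0.20 for glycolysis (-0.19), -0.45 for branched-chain synthesis (-0.60) and -0.17 for polysaccharide synthesis (-0.16), and the type VI mean was 0.65 (0.72). The branched-chain mean was then -0.21 (-0.40). With the trend against coding length removed the tRNA synthetase, glycolysis, branched-chain and polysaccharide calls were lost (0.0537 to 0.0559) at medians of -0.16, -0.17, -0.56 and -0.13. With thinned libraries the polysaccharide and type VI calls were lost (0.063 and 0.0756; median -0.15 and mean 0.72), and with no filter the branched-chain call (0.0676; median -0.59). The third biofilm library, like the third planktonic one, lay apart on the second component and held the most peg.2750 transcript of its group, 706 CPM.

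The mucus differences in the 2 states, from separate libraries, shared 63 genes higher with mucus (14.0 by chance overlap of independent lists) and 30 lower (7.05), with 0 in opposite directions, and their Pearson correlation across genes was 0.537. Same-numbered planktonic and biofilm libraries without mucus deviated together, and both sets of calls came from the same fit with a shared spread per gene. These chance overlaps allow for neither. On log2 CPM the correlation was 0.527 and the covariance 0.130, where the deviations shared by same-numbered libraries alone would give an estimated 0.287 and 0.0174.

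Whether the biofilm effect differed with mucus was tested by the interaction. It passed for 19 genes, 16 with a more positive and 3 with a more negative biofilm effect with mucus. The balance turned to 54 and 64 without the third biofilm library without mucus, and to 89 and 127 without that and the third planktonic library. Carbonic anhydrase peg.565 had a difference of 1.44 on the log2 scale (SE 0.22, adjusted p = 0.0103) and peg.2568 (3056124–3058466), a conserved protein without assigned function, 1.75 (SE 0.22, adjusted p = 0.00768). The glycosyl hydrolase peg.1316 (1532083–1534626) and AepA peg.1324 (1548984–1550612), annotated as a regulator of exoenzymes, had 1.07 and 0.98 (adjusted p = 0.0439 and 0.0489). All 3 negative genes are annotated as regulators, and the annotation ties peg.101 and peg.1433 to phosphate. They were the response regulator peg.100 (116412–117095; -1.56, SE 0.24, adjusted p = 0.0103), its neighbour PhoR peg.101 (117095–118150; -1.19, adjusted p = 0.0311), the sensor of the phosphate regulon, and the PhoU-like peg.1433 (1689647–1690300; -0.97, adjusted p = 0.0103). The response regulator peg.100 was at 561 ± 124 CPM in biofilm and 262 ± 24.2 in biofilm with mucus, and at 354 and 488 in the planktonic groups. The coding sequences peg.100 and peg.101 overlap by their coordinates, so reads there cannot be assigned with certainty.

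The count for the interaction ran from 8 without the first or the second planktonic library with mucus to 118 without the third biofilm library without mucus, and was 61 with the replicate number as a block within each treatment. It was 80 without the third planktonic, 37 without the first, 9 without the third planktonic library with mucus, 11 without the second biofilm library or the first or second biofilm library with mucus, and 12 without the third of those. The calls of peg.1316, peg.1324 and peg.101 were lost without 8, 9 and 8 of the 12 libraries, each left out in turn, with adjusted p up to 0.10, 0.11 and 0.082. With thinned libraries peg.1316 and peg.1324 had 0.0752 and 0.0722, and peg.1324 had 0.0519 under total-count scaling. With the replicate number as a block peg.1324 had 0.0524, at a difference of 0.99, and with the block within each treatment it passed. The other 4 kept theirs. The ribosomal protein list (adjusted p = 0.00582, median 0.23) and the type VI list (0.0282, median 0.24) passed, with 0 of 53 and 0 of 7 members past the gene test (0 and 3 adjusted over the list alone). Neither passed with an estimated correlation (adjusted p = 0.895 with an estimated correlation for both) or with the trend against coding length removed (0.11 and 0.095), nor the type VI list with thinned libraries (0.227). The ribosomal call was lost without the third planktonic library (0.0669) or the third biofilm library with mucus (0.315), while the type VI call was lost without the first or second planktonic (0.0916 and 0.15), the third biofilm (0.184), the first planktonic with mucus (0.0563) or the first biofilm library with mucus (0.114). The ribosomal median was 0.17 with the length trend removed and 0.14 and 0.09 without those libraries, and the type VI mean 0.61 to 0.68 against 0.70 in the fits that lost it.

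**Figure D5:**
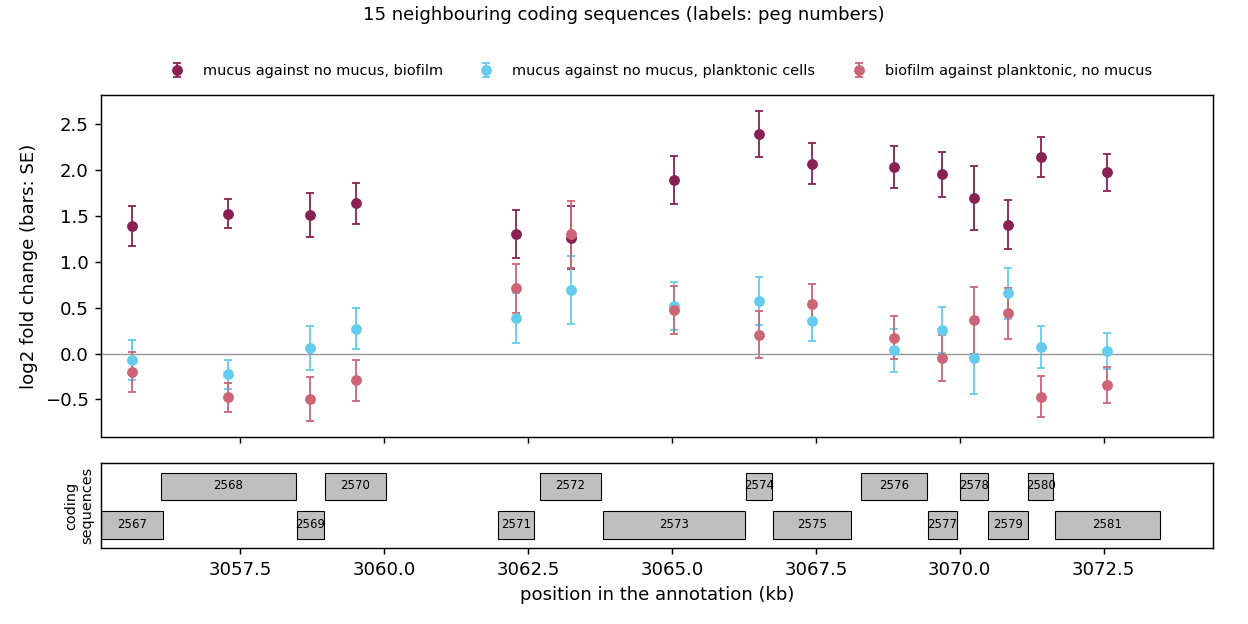
Log2 fold changes with SE bars of 15 neighbouring coding sequences, peg.2567 to peg.2581, by position in kb, for mucus against no mucus in biofilm and in planktonic cells and for biofilm against planktonic cells without mucus, above a map of the sequences; the region was chosen after its values were seen. With mucus in biofilm the changes lie between 1.26 and 2.39, and no planktonic change with mucus passed.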

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

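The list test of the interaction and the tests of the third libraries, whole pairs, batches, a single library and the ribosomal protein list were chosen only after the result was seen.

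The interaction tests directly whether the biofilm effect differs with and without mucus, and it passed for 19 genes. Of the named genes, the log2 difference was 1.75 for peg.2568 (adjusted p = 0.00768), 1.44 for carbonic anhydrase peg.565 (0.0103), 1.07 for glycosyl hydrolase peg.1316 (0.0439) and 0.98 for AepA peg.1324 (0.0489). It was -1.56 for the response regulator peg.100 (0.0103), -1.19 for PhoR peg.101 (0.0311) and -0.97 for PhoU-like peg.1433 (0.0103). The ribosomal protein and type VI lists passed with adjusted p = 0.00582 and 0.0282, and neither passed with an estimated correlation (adjusted p = 0.895 with an estimated correlation for both). When mucus labels were exchanged within each state, which breaks up the same-numbered pairs, 11 of 100 drawn splits, the real one included, gave at least 19 genes and 56 gave at least 2 lists, so these splits do not exclude chance for either count. The highest of the other splits gave 106 genes and 12 lists. All 10 other splits with at least 19 genes, that one included, kept the biofilm libraries parted by mucus and mixed the planktonic ones, so their counts hold the mucus difference in biofilm, and the highest of the 86 that mixed the biofilm libraries gave 1 gene. Mixing the biofilm libraries puts the mucus difference into the spread within groups and lowers the count, so these 86 give no chance level for 19. When whole pairs were exchanged, the real split gave 19 genes, or 61 with the pair as a block, and the highest other gave 0 in both, with 1 of the 10 splits as large, and 10 splits are too few for a share under 0.05. Without the block, exchanged pairs likewise carry the mucus difference in the spread within groups.

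The 16 genes with a positive difference hold 9 from a pair of stretches, peg.2568 to peg.2581 and peg.2232 to peg.2236. When the positive genes were found without the first, second or the third biofilm library with mucus, the library left out lay above all 9 libraries of the other groups in 9 of 9, 9 of 9 and 8 of 10 genes, which argues against a single library as the source of the pattern. With every library thinned to the same total the median difference was 1.72 against 1.73, but random thinning leaves expected changes as they are, so the bound written beforehand was no test of depth, which stays open. Chance stays open for the number of genes. The other large splits among the 100 held the mucus difference in biofilm, and the 10 splits of whole pairs are too few to decide. A response to mucus that is larger in biofilm is the biological candidate explanation for 13 of the genes. The genes peg.1324, peg.5 and peg.1212 were instead lower with mucus in planktonic cells (-0.69, -0.62 and -0.64, against 0.29, 0.29 and 0.03 in biofilm, which did not pass). A batch difference that moved both states alike would cancel in the interaction. A batch difference that moved the states unequally stays open for all 16, because the labels give no batch.

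Mucus went with 324 changed genes in planktonic cells and 330 in biofilm, where the highest of the other 9 splits gave 0 in each, and 10 splits are too few for a share under 0.05. In biofilm 302 of the 330 passed again without both the third planktonic and the third biofilm library, and 241 without the latter alone. This argues against those libraries as the source of most gene calls. Of the 7 lists, 1 passed again without both and 0 without the latter. The list medians, or the mean for type VI, kept most of their size as the report gives. The branched-chain mean did not, at -0.21 in both fits against -0.40 with all libraries. It was also -0.24 without the second biofilm library. The part of the third libraries in the list calls thus cannot be told apart from that of fewer libraries. In planktonic cells 226 of the 324 passed again without both but 88 without the third planktonic library alone, where the changes had the same sign in 324 of 324 and a median of 0.884 times their size but peg.2750 went from -4.12 to -1.51, so the part of that library cannot be told apart from a mucus difference. After thinning, 125 of the 324 and 190 of the 330 passed again, with 324 of 324 and 329 of 329 changes of the same sign at a median of 0.994 and 0.992 times their size: the planktonic number lies below the bound written beforehand for depth, but random thinning loses weak calls and keeps expected changes by construction, so neither value tests depth, which stays open. The mucus differences of the 2 states correlated at 0.537 across genes (0.527 on log2 CPM, against an estimated 0.287 from same-numbered libraries that deviate together), and a common response to mucus and a difference between batches of cultures or libraries cannot be told apart because the labels give no batch.

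Ribosomal protein genes were higher in biofilm by a median of 0.51 without and 0.76 with mucus on the log2 scale. With the trend against coding length removed the medians were 0.50 and 0.66, which argues against length as the whole cause. The lowest medians over 3 scalings were 0.41 and 0.65, both under total count. That scaling moved the median of all genes only to -0.11 in each comparison, too little to bring the list to 0. The rise thus does not hang on the choice among these scalings, and a larger shift was not tested. The library medians of the list were 10.42, 10.33 and 10.80 log2 CPM in biofilm against 9.80, 10.05 and 10.15 in planktonic cells, and 10.16, 10.18 and 10.57 against 9.54, 9.76 and 9.63 with mucus. Exchanging the state within each treatment gave p = 0.005 in an exact two-sided permutation test of these 12 medians, and p = 0.0312 when it was exchanged within same-numbered pairs, each the smallest such exchanges can give, and 0.015 and 0.0312 when any of the 30 lists could go as far in units of its spread, which argues against variation of the whole list between replicate cultures over both treatments together. A difference in growth between attached and free cells is the biological candidate explanation and was not measured here, and batches of libraries by state stay open because the labels give none.

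The other counts compared with splits of the same libraries were as follows, and 10 splits are too few for a share under 0.05. Biofilm against planktonic cells gave 614 genes without mucus and 907 with it, and the highest other splits gave 66 and 0, so that 1 of the 10 splits, the real one, was as large in each of the 4 comparisons. Without mucus, where the replicate numbers pair the libraries by the criterion given, the other 3 splits that part all 3 pairs gave 0 genes and the 6 that part 1 pair gave 0 to 66. Gene lists passing were 9, 4, 1 and 7 in the order of the report, and the highest other splits gave 10, 7, 8 and 9, with 2, 4, 7 and 2 of the 10 splits as large, the real one included.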

How the results depend on the processing

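Leaving out the third planktonic and the third biofilm library without mucus, removing the trend against coding length, thinning to the shallowest total, the replicate block within each treatment and every setting of the list test of the interaction were chosen after seeing the data. Values stand in the order of the report: biofilm without mucus, biofilm with mucus, mucus in planktonic cells, mucus in biofilm, interaction. Numbers of genes were 614, 907, 324, 330 and 19, and stayed within 1.5 times of these under both other scalings, without the filter, with the length trend removed and with the replicate block (644, 932, 294, 341 and 24). The replicate block within each treatment gave 61 for the interaction. The DESeq2 test gave 538 for mucus in planktonic cells and 145 for the interaction. Only the libraries compared in the fit gave 113, 1389 and 101 for the first 3. Replicates varied more without mucus than with it (Spearman correlations of 0.969 to 0.990 against 0.994 to 0.997). The fit of all 12 libraries shares an estimate of spread between them, so the counts of 614 and 907 do not compare the effects in size. For the counts under these settings the cause was not tested. An adjusted p below 0.01 left 223, 493, 17, 111 and 2 genes and a minimum fold of 2 left 124, 225, 70 and 132, fewer by construction. Without the third libraries 528 genes passed for mucus in biofilm and 216 for the interaction, 89 more positive and 127 more negative, with all 19 first calls among them, and the cause was not tested. After thinning 131, 207 and 12 genes passed in the last 3, with 125, 190 and 10 of the first calls among them, since it removes counts. With each library left out in turn the numbers ran from 351 to 680, 569 to 702, 11 to 512, 125 to 370 and 8 to 118, and the report names each library that moved them by over 1.5 times.

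Numbers of passing lists were 9, 4, 1, 7 and 2. An estimated correlation left 1, 1, 0, 0 and 0, which is a larger allowance for members that vary together. The direction test of fry gave 12, 2 and 0 for the second, the third and the last, and its mixed test 29, 29, 28, 24 and 11, since neither compares a list with other genes. The direction test missed lists that passed camera. Without mucus these were chaperones (adjusted p = 0.081) and low-oxygen genes (0.0857), and for mucus in planktonic cells ribosomal proteins (0.103). For mucus in biofilm they were low-oxygen and branched-chain genes (both 0.0569), and for the interaction the ribosomal (0.404) and type VI lists (0.268). The mixed test missed the histidine, tryptophan and arginine list for mucus in biofilm (0.0706) and the ribosomal list for the interaction (0.203). Without the third libraries 3, 1 and 4 passed in the last 3. Removing the length trend gave 2, 4 and 0 there, and thinning 2 for mucus in planktonic cells and 1 for the interaction. The cause of these was not tested. With each library left out the numbers of lists ran from 3 (without the first planktonic or the third biofilm library) to 10, stayed at 4 with mucus, ran from 1 to 10 (without the first planktonic library; 3 without the third and 4 without the first with mucus), from 0 (without the third biofilm library) to 10, and from 1 to 3.

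For biofilm without mucus, where the numbers pair the libraries by the criterion of 0.1, the replicate block changed no call of a named gene, and of the lists only the histidine, tryptophan and arginine call given in the report. Same-numbered libraries correlated at 0.0228 to 0.183 with mucus, at -0.0221 to 0.071 for mucus in planktonic cells and at -0.0308 to 0.0408 in biofilm. Not every pair was above 0.1 there, so by this criterion the numbers do not pair those libraries. Low correlations do not show that they came from different flasks. With mucus, 2 of the 3 pairs of biofilm and planktonic libraries matched best with their own number, as without it. In the comparisons that missed the criterion the block lost 5 calls, of peg.677, peg.2752, peg.2753, peg.2755 and peg.332, which is not read as a weaker effect. For the interaction, part of whose libraries the numbers pair by this criterion, the block lost peg.1324 (adjusted p = 0.0524). Of 298 named values, 5 lost their call under DESeq2 size factors, 13 under total count, 4 without the filter, 0 of 296 in the DESeq2 test, 106 of 291 with only the libraries compared, 19 without the third libraries, 5 with the length trend removed and 67 after thinning. With 1 library left out, each fit covered 146 to 159 named values, and from 13 of 146 to 60 of 159 lost their call. Of 642 losses over all settings 625 stayed within 1.5 times their size. No alternative weakened or reversed 27 of 83, 79 of 95, 9 of 57, 27 of 56 and 4 of 7. Genes that had not passed at first could not count as weakened, and 81, 94, 54, 53 and 7 had passed. Reversed were peg.646 in biofilm with mucus (from 0.11 to -0.0052 without the second planktonic library with mucus, range -0.0052 to 0.17) and peg.2295 for mucus in biofilm (from 0.22 to -0.076 without the second biofilm library, range -0.076 to 0.58), neither of which passed at first (adjusted p = 0.722 and 0.686), and the cause was not tested. DESeq2 gave no adjusted p for catalase peg.758 in either biofilm comparison (log2 change 5.49 and 4.88). These values are therefore not among the 296, and that test did not uphold the catalase calls. The cause of the missing value was not tested. Depth and 3 replicates limit small changes: 1.5-fold changes were found in 32.8% to 38.8% of simulated cases and in 8.96% for the interaction, with the same spread simulated in all groups.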

Other observations

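Some changed genes lay in runs of at least 4 neighbours that passed in the same direction, a rule and a set of regions chosen after the values were seen. There were 25 such runs in biofilm without mucus, 41 in biofilm with mucus, 6 for mucus in planktonic cells and 17 for mucus in biofilm. They held 119 of 614, 217 of 907, 32 of 324 and 96 of 330 changed genes, where 1000 random placements of the calls along the chromosome gave means of 3.73, 16.7, 0.316 and 0.489 and at most 20, 49, 8 and 12. The longest held 15 genes, peg.2567 to peg.2581 (3055088–3073478), among them a ClpB protein, peg.2573, and a Spr-type lipoprotein, peg.2571. With mucus in biofilm its genes rose by 1.26 to 2.39 on the log2 scale, no member passed for mucus in planktonic cells, and the interaction passed for 6 of them. Runs with Vgr spike genes rose with mucus in biofilm as well, at peg.355 to peg.359 (438217–443026, 0.69 to 2.97), peg.547 to peg.553 (669821–677506, 0.87 to 1.85) and peg.2620 to peg.2627 (3112466–3121284, 1.12 to 2.14). A carotenoid synthesis run, peg.527 to peg.533 (645750–652788), makes the class of pigment to which the yellow of many flavobacteria belongs, and it rose by 0.78 to 1.70 with mucus in biofilm. In it phytoene synthase peg.529 changed by 1.70 (adjusted p = 0.00183), beta-carotene hydroxylase peg.530 by 1.55 (0.00136) and lycopene cyclase peg.531 by 1.06 (0.00755), all at low levels, with 27.0 ± 4.09, 15.7 ± 1.75 and 13.5 ± 0.735 CPM (SD, n = 3) in biofilm with mucus.

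A nitrate and molybdenum cofactor stretch also rose with mucus in biofilm: the nitrate/nitrite transporters peg.1149 and peg.1150 by 1.94 and 2.05 (adjusted p = 0.0334 and 0.0348) and MoaA peg.1151 by 1.33 (0.0226). Siroheme synthase peg.2222 and the sulfite reductase subunits peg.2224 and peg.2225, of sulfur assimilation, were lower there by -1.13, -1.22 and -1.23 (adjusted p = 0.0387, 0.0453 and 0.0371). In biofilm against planktonic cells the iron-sulfur cluster assembly run peg.189 to peg.193 (220887–226133) was higher by 1.06 to 1.38 without mucus and 1.03 to 1.35 with it, and the ferric citrate transporter run peg.1292 to peg.1295 (1506072–1512363) by a median of 1.95 and 2.77. Siderophore synthesis genes peg.2097 and peg.2098 changed by 3.12 and 3.40 without mucus (adjusted p = 0.0349 and 0.0297), from levels of 1.22 ± 0.45 and 1.87 ± 1.01 CPM. The ATP synthase run peg.81 to peg.86 (97059–102200) was higher in biofilm with mucus by 0.65 to 0.84. In planktonic cells with mucus, lower runs held the rhamnose and glycan genes peg.62 to peg.67 (76205–82963, -0.86 to -0.37), the Bat genes peg.229 to peg.232 (272373–276841, -0.75 to -0.49) and a phage antirepressor with its neighbours, peg.146 to peg.152 (166586–170418, -2.13 to -1.44). Single calls in these runs were not followed through every alternative, and those for mucus carry the dependence on single libraries given in the report.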
